A study of Danio rerio with 9 samples.

How the data were processed

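Gene expression was measured in whole zebrafish larvae at 5 days post fertilization on single-colour (Cy3) Agilent arrays, 1 array per sample and 3 samples per group. The labels state 3 independent experiments per group. Control and neomycin larvae were kept in 1% DMSO during the 1 h of pretreatment per the labels, and for the larvae given tacrine no DMSO level is stated. Labelled RNA was made from 0.2 µg of total RNA with a low-input amplification kit.

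The authors deposited 1 scanner file per array, whose values are intensity on a linear scale per the file headers: a processed signal, corrected for background by Feature Extraction, and median signals of spot and local background. The deposited quality columns, in another unit (0 or 1), mark spots well above background, saturated spots and outlier spots. The file headers name Feature Extraction 10.1.1.1, whereas the authors' notes name version 8.0. The authors also deposited a matrix of log2 values for 25265 of the probes. Its 9 columns have medians of 7.11 or 7.12 and a lowest value of 5.66, each correlates with its own array at r between 0.981 and 0.986, and each matches its own array best after centring; the method behind it is not stated. It was used as an alternative only. The headers date the array design to an older genome build, so no positions are given.

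Spots of 1 probe were averaged on the log2 scale. From the log2 processed signal the 75th percentile over the non-control probes of each array was subtracted. Of 43603 probes, 31671 that were well above background on at least 3 of the 9 arrays were tested and 11932 were not. No probe was saturated, and between 3 and 9 spots per array were marked as outliers. Probes were named through the RefSeq accession that the array files give, matched to the gene symbols of the GRCz12tu assembly: 25173 probes have 1 symbol, from 12900 genes, and 18430 have none. Of the list members, 22 were matched by an older symbol, and a few of these stand for another gene (the lists' clps, foxq1a, pdk2a and nefla were matched to nsg2, foxq1b, pdk2b and neflb).

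Comparisons, tests, gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, with the exceptions named below. The 3 comparisons were neomycin against control, both compounds against neomycin, and both compounds against control. All were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 6 residual and 3.11 prior degrees of freedom, two-sided). A probe was called at a Benjamini-Hochberg adjusted p under 0.05, and values are log2 differences with the moderated standard error. Adjusted p values of single probes and genes below are from this model. Those of gene lists are from camera, described below. The fit was tested on simulated data with each probe's mean and spread and no group differences except 100 probes changed by 1 and 100 by 2 on the log2 scale: 44% to 49% of the first and 88% to 96% of the second were called, with 3 to 5 false calls.

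The genes named are, per comparison, the 10 largest rises and the 10 largest falls among called probes whose groups do not overlap and whose symbol is a gene name, up to 4 members with the smallest p from each list, and ache, cyp1a, atoh1a, pou4f3, fosab, hsp70l, hmox1a and il1b throughout. Where 1 gene has several probes, the called one with the smallest p stands for it in the first group and the brightest one in the lists, so its values can differ. Members of lists that did not pass are mostly given where they passed themselves. List members named beyond 4 per list were named after their values were seen. A few list members that the rule picks are not reported here. In neomycin against control 5 genes qualified as falls.

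The 32 gene lists are hair cells, neuromast support cells, oxidative stress, aryl hydrocarbon receptor targets, drug metabolism, immediate early genes, heat shock, the integrated stress response with the unfolded protein response, apoptosis, inflammation, leukocytes, cholinergic genes, glucocorticoid response, clock genes, photoreceptors, skeletal muscle, liver, exocrine pancreas, islet and enteroendocrine cells, intestine, epidermis, neurons and glia, lens, erythroid cells, cartilage and bone, ionocytes and pronephros, cell cycle, lipid synthesis, lysosome, glycolysis and hypoxia, ribosomal proteins and oxidative phosphorylation. The ribosomal list was taken by symbol and also holds rps6kal, named after a kinase. With 1 probe per gene, 11326 genes were compared by camera with a preset correlation of 0.01, adjusted over the 32 lists of a comparison. Members are counted by this probe, the brightest, and another probe of a member can pass where it does not. A list's shift is its mean log2 difference minus that of all other genes. Camera with an estimated correlation and fry were run as alternatives. Fry, which tests a list without reference to other genes, called 2, 6 and 11 lists in the 3 comparisons.

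Correlations between comparisons were set against 100 simulated data sets with no group effect. Random lists of 41 genes, 10000 in number and matched on mean signal, were compared with the immediate early list. Replicate numbers match slides, so a block of the replicate number is also a block of the slide. The alternatives were quantile normalization, median centring, a 75th percentile over probes well above background on all 9 arrays, no filter, a filter on all 9 arrays, the authors' matrix, the block, only the arrays compared, eBayes with trend and robust estimation, array weights, a floor under dim signals, an adjusted p under 0.1, a change of at least 2-fold, removal of outlier spots, the mean over the probes of a gene, and leaving out each array in turn. A background correction on mean signals could not be run, because the deposited files hold no such column. After the data were seen, normexp (offset 50) on median signals was added in its place, with the same scaling and with quantile normalization. Normexp differences printed below for single genes are set against the median of all probes. Unused columns of the scanner files were not analysed here.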

Results

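RNA of whole zebrafish larvae at 5 days post fertilization was measured on 9 single-colour arrays, 3 per group. Control larvae received neither compound. The neomycin group received neomycin at 200 µM for 1 h; neomycin is an aminoglycoside antibiotic that kills sensory hair cells of the inner ear and the lateral line. The group given both compounds received tacrine, an inhibitor of acetylcholinesterase, at 50 µM for 1 h and then neomycin at 200 µM for 1 h. The labels give no group with tacrine alone, so the action of tacrine without neomycin and its interaction with neomycin cannot be estimated. They state 1% DMSO for control and neomycin larvae and no level for larvae given tacrine. A difference in DMSO therefore cannot be told apart from tacrine. The 75th percentile of the signal on the 3 arrays was 115, 105 and 137 in controls, 170, 142 and 164 with neomycin and 226, 152 and 174 with both compounds. Of 43603 probes, between 28595 (65.6%) and 32191 (73.8%) were well above background on an array, and 31671 were tested. Replicate arrays correlated across probes with r between 0.98 and 0.986, and arrays of different groups with r between 0.967 and 0.983. The first principal component held 29.1% of the variance and set the arrays with both compounds (46.5 to 65.1) apart from the others (-45.9 to -19.5); the second held 18.7%. The arrays came on 3 slides, each with 1 array per group. Controls always lay at place 1, neomycin at place 3 and both compounds at place 4, so place on the slide and group cannot be told apart. The number of arrays limits the precision: the median standard error of a log2 difference was 0.2.

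The comparison of neomycin with control larvae asks what 1 h of neomycin changes in the whole larva. Of 41 immediate early genes, which are transcribed within minutes of a stimulus, 5 rose and 36 did not pass. fosab, a subunit of the AP-1 transcription factor, rose by 2.59 on the log2 scale (SE 0.22, n = 3 per group, 6.01-fold, adjusted p = 0.00692) on its best probe, and 3 of its 5 tested probes passed. The zinc finger factor egr3 rose by 2.44 (SE 0.22, 5.44-fold, adjusted p = 0.00723, 1 of 2 probes), junbb by 1.29 (SE 0.17, adjusted p = 0.0426) and the stress factor atf3 by 1.59 (SE 0.22, adjusted p = 0.0436). When each of the 9 arrays was left out in turn, junbb no longer passed in 8 of the 9 fits and atf3 in 7. Mediators of inflammation rose as well: ptgs2b, which makes prostaglandins, by 2.25 (SE 0.25, 4.74-fold, 2 of 2 probes), the cytokine tnfb by 1.47 (SE 0.20, 2.77-fold) and the matrix protease mmp9 by 1.39 (SE 0.19, 2.62-fold). The largest fall among probes with a gene name that is no placeholder was that of anxa3a, which encodes an annexin that binds membranes in the presence of calcium: its 1 probe fell from a mean of -0.68 (SD 0.20) to -7.03 (SD 0.36), which is at least 23.3-fold lower (log2 difference -6.35, SE 0.29, adjusted p = 0.000104).

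"At least" marks a bound: where none of a group's 3 arrays showed the probe well above background, its values were raised to the lowest signal well above background on their arrays. The other named genes that rose with neomycin were the tumour necrosis factor receptor tnfrsf9a (2.53, SE 0.32), mettl13 (1.97, SE 0.27, 1 of 2 probes), the binding protein of insulin-like growth factors igfbp1a (1.95, SE 0.21, 3 of 3 probes) and grcc10, whose called probe was at least 3.16-fold higher and whose 2 other probes did not pass; normexp turned its direction (-0.15). pet117, an assembly factor of the respiratory chain, fell by 2.16 (SE 0.24), the ribosome-linked faub fell by 1.46 (SE 0.16, 1 of 3 probes) and naaladl1 fell by 1.03 (SE 0.15, 1 of 4 probes). asb5a was also called lower but was not well above background on any array of either group, so no value is given. On the 3 slides the difference was 2.45, 3.28 and 2.03 for fosab, 2.35, 2.73 and 2.25 for egr3 and -6.80, -5.85 and -6.40 for anxa3a. With the slide as a block, grcc10 (adjusted p = 0.0662), the probe of ptgs2b with the smallest p (0.0561), mettl13 (0.093), tnfb (0.0831), mmp9 (0.0693), pet117 (0.0595), asb5a (0.0569) and naaladl1 (0.0812) no longer passed.

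Of the 41 measured genes of the immediate early list, 5 rose (fosab, egr3, junbb, atf3 and the phosphatase dusp5, 1.25), none fell and 36 did not pass; 15 rose when adjusted over the list alone. The list lay 0.56 above the other genes (camera adjusted p = 3.87e-15; adjusted p = 0.126 with an estimated correlation), with 0.50, 0.74 and 0.43 on the 3 slides. Of 31 genes of inflammation, 3 rose (ptgs2b, tnfb and mmp9), none fell and 12 rose when adjusted over the list alone. That list lay 0.59 above the others (adjusted p = 7.21e-13; 0.366 with an estimated correlation), and its slides gave 1.11, 0.34 and 0.31; with normexp background correction the shift was 0.26 and no longer passed (adjusted p = 0.0738). No member passed over all probes in the 5 lists that lay lower. These were clock genes (-0.29, adjusted p = 0.00112; 0.184 with an estimated correlation; nr1d2a, nfil3-6, nr1d1 and tefb of 27 fell when adjusted over the list alone), exocrine pancreas (-0.31, 3.75e-06; 0.411), liver (-0.15, 0.028; 0.411), skeletal muscle (-0.20, 1.49e-06; 0.591) and ribosomal proteins (-0.17, 1.52e-06; 0.763). The shift of the ribosomal list turned to 0.01 with quantile normalization and with the authors' matrix. It was 0.64 with normexp and the 75th percentile scaling, which also turned pancreas (0.45), liver (0.47) and muscle (0.60) upward. With these reversed shifts the lists passed too. Camera gave adjusted p = 3.62e-07 for ribosomal proteins, 0.029 for pancreas, 0.00493 for liver and 6.82e-05 for muscle. With quantile normalization after normexp, only the ribosomal list turned (0.02). Pancreas and muscle then stayed lower and passed, and liver lay at -0.10 and did not (camera adjusted p = 0.141). Liver also failed with quantile normalization (adjusted p = 0.143), with no filter (0.142) and in the authors' matrix (0.0997), and muscle with quantile normalization (0.0533). The slides gave -0.56, -0.25 and -0.10 for pancreas, -0.32, -0.25 and -0.03 for muscle and -0.24, -0.22 and -0.06 for ribosomal proteins. The shift of pancreas was -0.18 without neomycin 1 and that of muscle -0.12 without control 1. That of ribosomal proteins was -0.05 without control 1, -0.27 without neomycin 1 and -0.07 without neomycin 2.

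Hair cell genes did not pass as a list in neomycin against control (17 measured, shift -0.18, adjusted p = 0.243), and no member passed over all probes. Of 46 genes written for this list, 26 were on the array and 17 were tested, and 4 of the 17 differences were positive. The RNA is of whole larvae, so a change limited to hair cells could be missed. When adjusted over the list alone, gfi1aa (0.59) rose and pvalb8 fell. The hair cell regulator atoh1a differed by -0.00 (SE 0.16, adjusted p = 1), the calcium-binding pvalb8 by -0.77 (SE 0.19, adjusted p = 0.222) and s100t by -1.04 (SE 0.35, adjusted p = 0.386). pou4f3 was not tested, since it was not well above background on enough arrays. The 20 measured markers of neuromast support cells, which surround hair cells in the lateral line, had a shift of 0.07 (adjusted p = 0.572) with none passing. The oxidative stress list had a shift of 0.03 (29 genes, adjusted p = 0.652), the apoptosis list -0.02 (36 genes, adjusted p = 0.652) and the heat shock list -0.03 (30 genes, adjusted p = 0.997), with no member of the 3 passing. Of 24 glucocorticoid response genes (shift -0.16, adjusted p = 0.467) igfbp1a rose, and hsd11b2, klf9, fkbp5, foxo3b and tsc22d3 fell when adjusted over the list alone. Among genes fixed for all comparisons, hmox1a, a heme-degrading enzyme of the oxidative stress response, differed by 0.02 (SE 0.28, adjusted p = 0.998), the chaperone hsp70l by -0.55 (SE 0.41, adjusted p = 0.789), ache, the gene of acetylcholinesterase, by 0.07 (SE 0.15, adjusted p = 0.953) and the detoxifying enzyme cyp1a by 0.51 (SE 0.19, adjusted p = 0.447). The cytokine il1b differed by 1.66 (SE 0.53, adjusted p = 0.359). It was well above background on no control array, so the size of this difference is uncertain.

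In all, neomycin against control gave 37 probes past the threshold, 27 higher and 10 lower, from 23 named genes (15 higher, 8 lower); 9 of the probes have no gene symbol. Each of the 37 changed at least 2-fold. At an unadjusted p under 0.05 there were 2857 probes (9.02%), and the 3 arrays of a group lay wholly above or below those of the other at 13.2% of probes, where chance gives 10%. With the slide as a block, 17 probes were higher and 5 lower, and leaving out 1 array gave between 11 and 65 calls. The excess of higher probes was not stable: 4 were higher and 7 lower without neomycin 2, 31 and 34 without neomycin 3, and 95 and 102 with array weights. Camera called 7 gene lists, and other splits of these 6 arrays into 3 and 3 gave up to 11. Mean, median and test differed in sign for the lists of cell cycle (mean -0.02, median 0.04), cholinergic genes (-0.02, 0.01), oxidative phosphorylation (0.02, -0.00) and oxidative stress (0.03, -0.04), and the lysosome list had a shift of 0.00 with a test that pointed down.

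**Figure D1:**
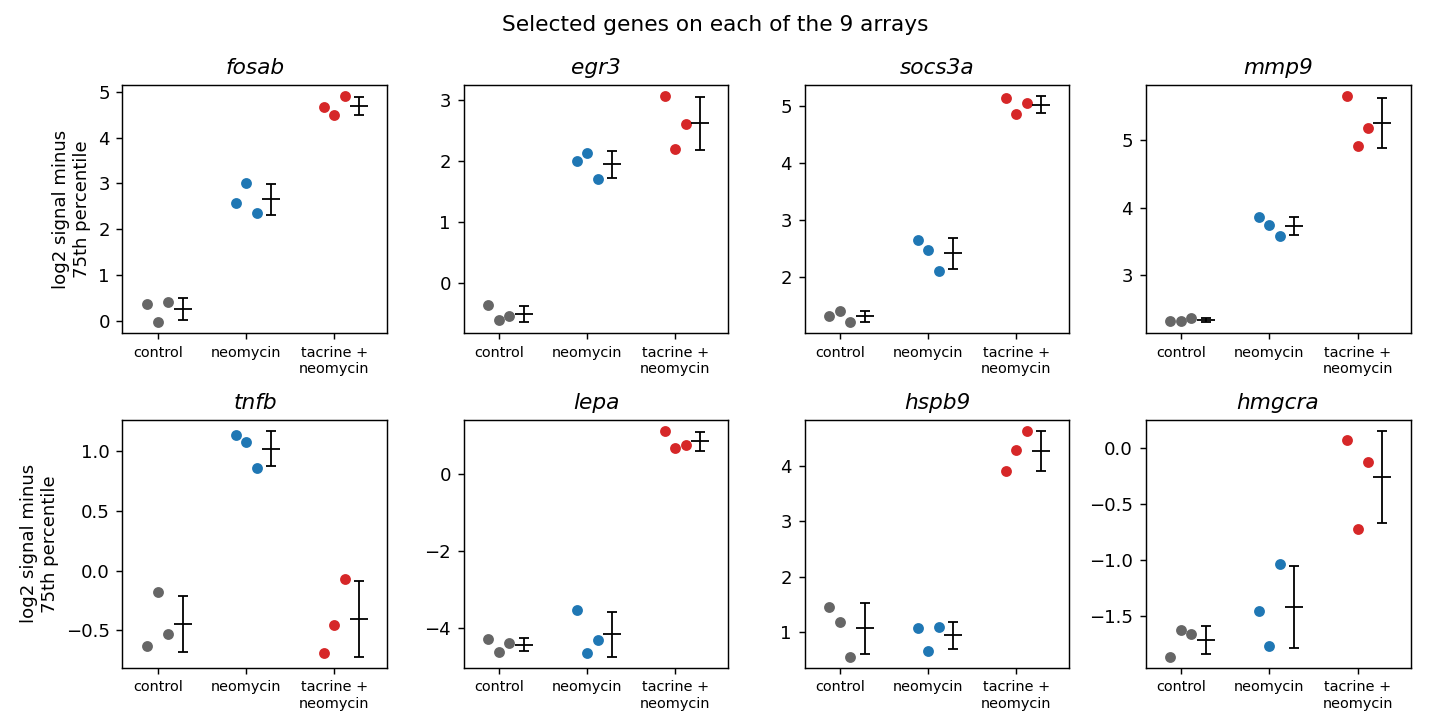
Scaled log2 signal of 8 genes on each of the 9 arrays (points; log2 signal minus the array's 75th percentile on the vertical axis), with the mean and SD of each group of 3 beside them. fosab stood highest with both compounds (mean 4.69) and lowest in controls (0.26), whereas tnfb was highest with neomycin alone (1.02).

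The comparison of both compounds with neomycin alone asks what pretreatment with tacrine changes in larvae that then receive neomycin. Of the 41 immediate early genes 20 rose. fosab rose by 2.03 (SE 0.21, n = 3 per group, adjusted p = 0.00245, 5 of 5 probes), socs3a, a brake on cytokine signalling, by 2.61 (SE 0.17, 6.10-fold, adjusted p = 0.000448), btg2 by 1.63 (SE 0.13, 3.09-fold) and the phosphatase dusp1 by 1.52 (SE 0.14, 2.87-fold). The gene of the hormone leptin, lepa, rose by 4.98 (SE 0.27, 31.6-fold, adjusted p = 0.000167). Its paralog lepb rose by 4.98 (SE 0.65, adjusted p = 0.00674), with 1 of 3 neomycin arrays well above background. The small heat shock protein hspb9 rose by 3.33 (SE 0.27, adjusted p = 0.00114) and the chaperone partner bag3 by 2.88 (SE 0.27, 7.35-fold). anxa3a was at least 20.8-fold higher than with neomycin alone (6.19, SE 0.29, adjusted p = 6.66e-05) and differed from the control level by -0.17 (SE 0.29, adjusted p = 0.792).

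Further rises were those of arl14 (3.40, SE 0.34), fkbp5, a target of the glucocorticoid receptor (3.38, SE 0.57, 1 of 2 probes), the muscle protein xirp1 (3.11, SE 0.24), the clock repressor bhlhe41 (2.99, SE 0.28) and the yolk protein vtg7 (2.77, SE 0.49, with 1 of 3 neomycin arrays well above background). The 10 named genes that fell most were led by stard8 (-3.71, SE 0.50, 13.1-fold lower, 2 of 3 probes). The gap junction gene gjc4a.2 was at least 3.53-fold lower, plekhs1.1 at least 1.90-fold, the antiviral kinase pkz at least 3.79-fold, plekhs1.2 at least 1.44-fold, the cytokine tnfa at least 2.52-fold and snx10a at least 3.25-fold. The sulfotransferase sult5a1 (-2.15, SE 0.35), the carotenoid-cleaving bco2b (-2.14, SE 0.42) and the chemokine cxcl20 (-2.06, SE 0.42) fell too. Slides gave 4.62, 5.29 and 5.03 for lepa, -4.64, -4.68 and -1.82 for stard8 and -2.91, -3.82 and -0.48 for pkz. With the slide as a block, pkz (adjusted p = 0.0823), plekhs1.2 (0.0766), tnfa (0.0651) and cxcl20 (0.0748) no longer passed.

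None of the immediate early genes fell with both compounds against neomycin alone and 21 did not pass; 31 rose when adjusted over the list alone. The list lay 0.99 above the other genes, with 1.07, 0.77 and 1.11 on the 3 slides (camera adjusted p = 5.78e-28; adjusted p = 0.0262 with an estimated correlation). It was the only list in this comparison that passed with an estimated correlation. Of 31 genes of inflammation, 6 rose and 3 fell: socs3a, socs3b (1.84), mmp9 (1.52), socs1a (1.57), ptgs2a (1.01) and il13ra1 (1.06) were the first, and tnfa, tnfb (-1.43, SE 0.20, adjusted p = 0.00806) and the interferon factor irf1a (-1.15) were the latter. That list had a shift of 0.35 (adjusted p = 0.00876; 0.712 with an estimated correlation) that varied between slides (0.06, 0.30 and 0.67) and, with no filter, was 0.19 and no longer passed (adjusted p = 0.0989). It was 0.53 without neomycin 1 and 0.19 without neomycin 3. Adjusted over the list alone, 10 rose and 5 fell.

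Clock genes rose in 5 of 27 cases, namely bhlhe41, nfil3-6 (1.56, SE 0.17), nr1d1 (2.13, SE 0.38), per1b (1.03, SE 0.16) and bhlhe40 (0.79, SE 0.16), and 6 rose when adjusted over the list alone; the shift was 0.56 (adjusted p = 2.23e-05; 0.0548 with an estimated correlation). Of 24 glucocorticoid response genes, hsd11b2 (1.34, SE 0.21) and the kinase sgk1 (1.09, SE 0.21) rose, 7 rose when adjusted over the list alone, and the shift was 0.43 (adjusted p = 0.00176; 0.0838 with an estimated correlation). Erythroid genes had a shift of 0.41 (adjusted p = 0.000146; 0.0838 with an estimated correlation): nt5c2l1 (0.72), ucp3 (2.04), slc4a1a (0.92) and gata1a (1.12) rose of 25, and 6 when adjusted over the list alone. With the slide as a block, ucp3 (adjusted p = 0.0794), slc4a1a (0.0663) and gata1a (0.0582) no longer passed. When each array was left out in turn, ucp3 and slc4a1a no longer passed in 8 of 9 fits and nt5c2l1 and gata1a in 7. Of 30 heat shock genes hspb9 and bag3 rose, and 8 rose and dnajb1b fell when adjusted over the list alone (shift 0.54, adjusted p = 0.000146; 0.233 with an estimated correlation). hsp70l differed by 1.05 (SE 0.41, adjusted p = 0.233).

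Lipid synthesis lay 0.31 higher (adjusted p = 0.00102; 0.387 with an estimated correlation), with the sterol synthesis genes hmgcra (1.16, SE 0.24) and hmgcs1 (0.99, SE 0.19; adjusted p = 0.0548 with the slide as a block) rising of 29. With each array left out in turn, hmgcra no longer passed in 7 of 9 fits and hmgcs1 in 6. The integrated stress response lay 0.21 higher (adjusted p = 0.0256; 0.548 with an estimated correlation), and 4 of 38 rose: ddit4 (1.96, SE 0.29), trib3 (1.06), atf3 (1.08) and slc3a2b (0.73; adjusted p = 0.0621 with the slide as a block). Glycolysis and hypoxia genes lay 0.17 higher (adjusted p = 0.00641; 0.394 with an estimated correlation), with hif1al (0.99) and slc16a3b (1.15) rising of 37. When adjusted over the list alone, 2, 5 and 4 members of these 3 lists rose, and pdk2b of the third fell. No member passed on its brightest probe in the 5 lists that lay lower: exocrine pancreas (-0.32, adjusted p = 0.000563; 0.451 with an estimated correlation), lens (-0.25, 0.0051; 0.712), lysosome (-0.16, 0.0447; 0.548), ribosomal proteins (-0.15, 0.000781; 0.847) and cell cycle (-0.13, 0.0454; 0.828; 0.0596 in the authors' matrix). The ribosomal shift was -0.05 with quantile normalization and no longer passed, and with normexp none of the 5 did (adjusted p = 0.0534 for pancreas, 0.145 for lens, 0.203 for lysosome, 0.415 for ribosomal proteins and 0.169 for cell cycle). With quantile normalization after normexp, ribosomal proteins (0.112) and cell cycle (0.0609) still failed. Ribosomal proteins also failed in the authors' matrix (0.0514), and lysosome with array weights (0.0781) or without outlier spots (0.0627). Cell cycle failed with array weights (0.179), with a filter on all arrays (0.0512) and with the percentile over probes above background on all arrays (0.0529). Ribosomal proteins lay at -0.06 without neomycin 1 and -0.26 without neomycin 2, and cell cycle at -0.08 without neomycin 1.

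The lists fixed for the drug target and the hair cells did not pass in this comparison. Of 36 cholinergic genes written, 18 were on the array and 15 were tested, with a shift of 0.02 (camera adjusted p = 0.842). The gene rapsn, which clusters acetylcholine receptors at the muscle synapse, fell by 1.04 (SE 0.17, adjusted p = 0.0176), and ache differed by 0.03 (SE 0.15, adjusted p = 0.942). The mean of that list was 0.01 and its median -0.05. Hair cell genes had a shift of 0.05 (adjusted p = 0.999) with none passing, and atoh1a differed by 0.18 (SE 0.16, adjusted p = 0.621). Among neuromast support markers stat3, a transducer of cytokine signals, rose (1.01, SE 0.17, adjusted p = 0.0201; list shift 0.14, adjusted p = 0.162), and the brighter probe of cldnb differed by 0.71 (adjusted p = 0.208) while 1 of its 2 probes passed as higher. Among targets of the aryl hydrocarbon receptor tiparp rose (0.96, SE 0.17; list shift 0.23, adjusted p = 0.181), while cyp1a differed by 0.53 (SE 0.19, adjusted p = 0.189). hmox1a differed by -0.01 (SE 0.28, adjusted p = 0.987) and il1b by 0.42 (SE 0.53, adjusted p = 0.735). The oxidative stress list had a shift of -0.06 (adjusted p = 0.842) with none passing. In other lists that did not pass, the apoptosis inhibitor xiap (1.02), krt18a.1 (0.99), apoa4a (1.59), slc20a1b (1.14) and pde6c (0.93) rose; with the slide as a block, apoa4a (adjusted p = 0.0569) and pde6c (0.0603) no longer passed.

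In all, both compounds against neomycin alone gave 844 probes past the threshold, 571 higher and 273 lower, of which 379 and 160 changed at least 2-fold. They came from 411 named genes (283 higher, 128 lower), and 282 have no gene symbol. At an unadjusted p under 0.05 there were 5527 probes (17.5%), and the groups did not overlap at 25.5% of probes, where chance gives 10%. With the slide as a block, 570 were higher and 279 lower, and leaving out 1 array gave between 272 and 976 calls. With array weights 1920 were higher and 1792 lower. Camera called 14 gene lists, and other splits of these 6 arrays into 3 and 3 gave up to 10. Mean and median differed in sign for the list of cartilage and bone (mean -0.06, median 0.04), and the test pointed up for islet and enteroendocrine cells (mean -0.06) and for liver (-0.01).

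**Figure D2:**
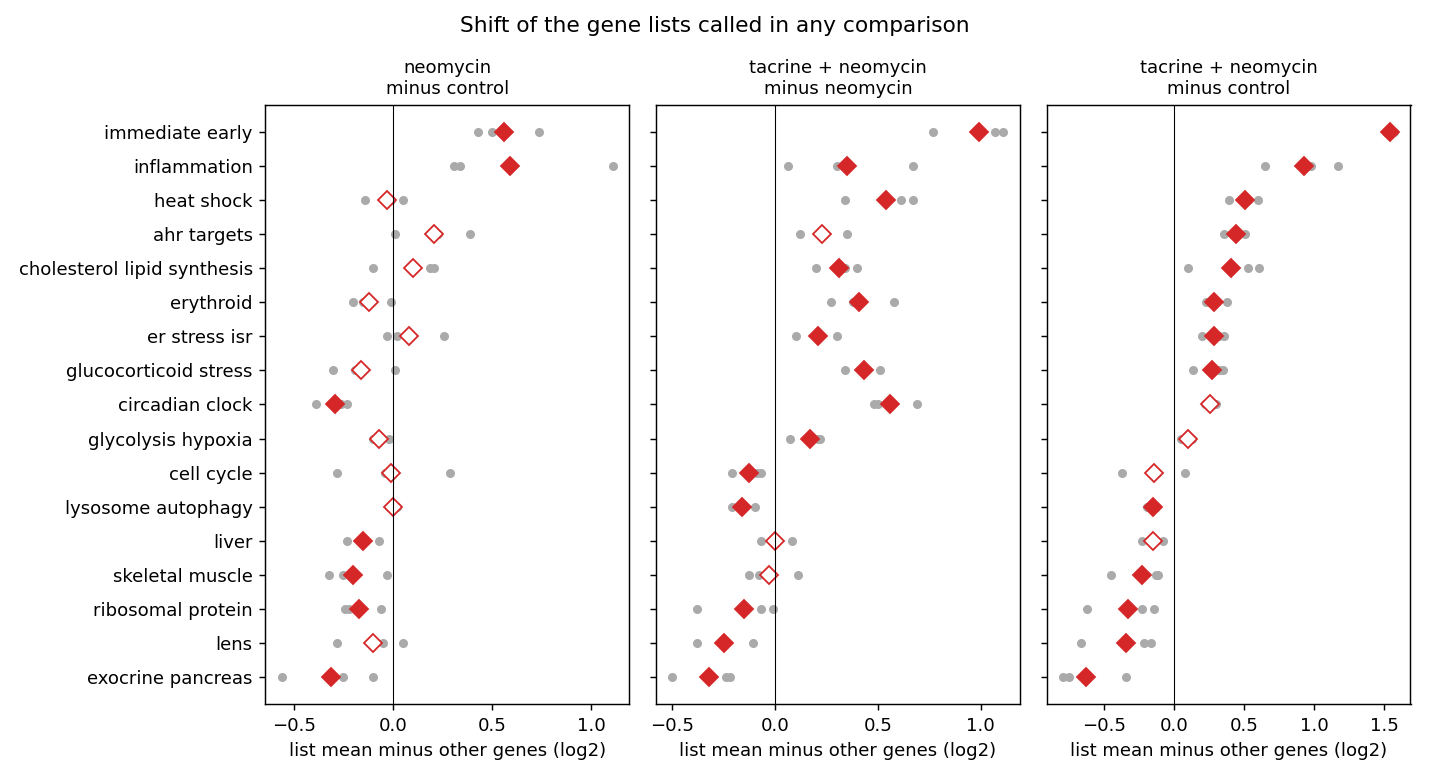
Mean log2 difference of each gene list minus that of the other genes (horizontal axis, log2), in the 3 comparisons, for the 17 lists called in at least 1 of them. Diamonds show the fitted value, filled where the camera adjusted p is under 0.05, and grey points the 3 slides; immediate early genes stood at 0.56, 0.99 and 1.54.

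The comparison of both compounds with control larvae gives the combined change. The leptin genes and the immediate early genes fosab and socs3a were among those that rose most. lepb was at least 14.4-fold higher (5.57, SE 0.65, n = 3 per group, adjusted p = 0.00214), lepa rose by 5.25 (SE 0.27, 38.1-fold, adjusted p = 4.48e-05, with 2 of 3 control arrays well above background), fosab by 4.42 (SE 0.19, 21.4-fold, 5 of 5 probes) and socs3a by 3.71 (SE 0.17, 13.1-fold, adjusted p = 2.83e-05). The AP-1 partner jdp2b rose by 3.29 (SE 0.17, 9.79-fold) and the chemokine ccl34a.4 by 3.54 (SE 0.44, 11.6-fold). hspb9 rose 9.21-fold (SE 0.27 on the log2 scale). Among probes with a gene name that is no placeholder, that of the secreted glycoprotein gene lgals3bp.2 fell most: it was at least 12.4-fold lower (-5.16, SE 0.90, adjusted p = 0.0145, 2 of 3 probes). The nuclear receptor nr4a3 was at least 2.91-fold higher on 1 of 2 probes, and its brighter probe differed by 0.25 (adjusted p = 0.384); normexp turned the direction of the first (-0.18).

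The collagen cross-linker loxl2a was at least 2.79-fold higher (2 of 2 probes; -0.16 with normexp), and rd3 rose by 3.81 (SE 0.76, 1 of 2 probes, 2 of 3 control arrays well above background) with 2.47, 2.58 and 6.39 on the 3 slides. Among named genes that fell, gjc4a.2 was at least 3.85-fold lower, fam167aa at least 2.23-fold, pkz at least 3.61-fold (adjusted p = 0.0593 with the slide as a block) and the receptor of interleukin 23, il23r, at least 2.76-fold. stard8 (-2.84, SE 0.50), plekhs1.3 (-2.30, SE 0.28, 3 of 3 probes), the acute phase gene crp6 (-2.11, SE 0.43), fam83fb (-2.08, SE 0.17, 4 of 4 probes; well above background on 1 of 3 arrays with both compounds) and faub (-2.08, SE 0.16, 3 of 3 probes) fell too. cyp1a, which did not pass in either step alone, was higher by 1.04 (SE 0.19, 2.06-fold, adjusted p = 0.0172, 2 of 3 probes). ache differed by 0.10 (SE 0.15, adjusted p = 0.742), atoh1a by 0.18 (SE 0.16, adjusted p = 0.56), hmox1a by 0.00 (SE 0.28, adjusted p = 0.997) and hsp70l by 0.49 (SE 0.41, adjusted p = 0.534). il1b differed by 2.09 (SE 0.53, adjusted p = 0.0537, and 0.0319 with the slide as a block). It was well above background on no control array, so the size of this difference is uncertain.

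Of the 41 immediate early genes, 30 rose, none fell and 11 did not pass; 32 rose when adjusted over the list alone. The list lay 1.54 above the other genes, with 1.57, 1.51 and 1.54 on the 3 slides (camera adjusted p = 1.13e-35; adjusted p = 0.0135 with an estimated correlation). No other list passed with an estimated correlation. Of 31 genes of inflammation, 11 rose, among them mmp9 (2.90, SE 0.19), socs3b (2.65, SE 0.18) and ptgs2b (2.52, SE 0.24), and irf1a (-0.85) fell. Adjusted over the list alone, 14 rose and 4 fell (shift 0.93, adjusted p = 1.46e-08; 0.249 with an estimated correlation). Of 30 heat shock genes, 6 rose, among them hspb9, bag3 (2.51, SE 0.27), hspa4a (0.95) and hspd1 (0.72); 11 rose and serpinh1b fell when adjusted over the list alone (shift 0.51, adjusted p = 0.000487; 0.242 with an estimated correlation). Of 29 lipid synthesis genes, 5 rose and tm7sf2 (-0.79) fell, with hmgcra (1.45, SE 0.24), hmgcs1 (1.04, SE 0.19), hmgcrb (0.87, SE 0.18) and sqlea (1.64, SE 0.36; adjusted p = 0.061 with the slide as a block) and nsdhl (0.73) the first. When adjusted over the list alone, 9 rose and 3 fell (shift 0.41, adjusted p = 0.000224; 0.242 with an estimated correlation), but with normexp the shift was 0.09 and no longer passed (adjusted p = 0.329).

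The integrated stress response lay 0.29 higher (adjusted p = 0.00706; 0.41 with an estimated correlation): 4 of 38 rose, namely atf3 (2.67, SE 0.22), trib3 (1.59), sesn2 (1.21) and mthfd2 (2.47-fold), and the chaperone calr (-1.03) fell. Erythroid genes lay 0.29 higher (adjusted p = 0.0116; 0.242 with an estimated correlation), with nt5c2l1 (0.64) and gata1a (0.96; adjusted p = 0.0543 with the slide as a block) rising. Glucocorticoid response genes lay 0.27 higher (adjusted p = 0.0441; 0.0693 with the slide as a block; 0.0685 with quantile normalization; 0.242 with an estimated correlation), with igfbp1a (4.93-fold) and sgk1 (1.06) rising. Targets of the aryl hydrocarbon receptor lay 0.44 higher (camera adjusted p = 0.0383), and tiparp (1.22), cyp1a and the receptor's repressor ahrra (0.80) rose of 11. That list failed with the slide as a block (0.0581), in the authors' matrix (0.068) and with no filter (0.144). It also failed with array weights (0.0577) and with an estimated correlation (0.242). When adjusted over the list alone, 9, 2, 5 and 4 members of these 4 lists rose. With normexp, the erythroid shift (0.19, adjusted p = 0.182) and that of the receptor targets (0.09, 0.708) no longer passed.

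Of 25 genes of the exocrine pancreas, which makes digestive enzymes, none rose and 5 fell over all probes, among them cel.2 (-0.95, SE 0.21), ela2l (-0.83, SE 0.15), ela2 (-0.71) and prss1 (-0.63, SE 0.15; adjusted p = 0.0542 with the slide as a block). When adjusted over the list alone, 19 fell. The shift was -0.63 (adjusted p = 4.26e-09; 0.242 with an estimated correlation) with -0.79, -0.75 and -0.34 on the 3 slides. Ribosomal proteins lay lower by -0.33 (adjusted p = 4.47e-10; 0.563 with an estimated correlation), and 2 of 85 fell, among them rpl14 (-0.98); their shift was -0.03 with quantile normalization and no longer passed. Lens (-0.34, adjusted p = 8.62e-05; 0.501 with an estimated correlation) had no member passing. In skeletal muscle (-0.23, 0.000487; 0.563) myhc4 fell, but the list no longer passed with quantile normalization (-0.08, adjusted p = 0.53) or in the authors' matrix (-0.06, 0.579). In lysosome (-0.15, 0.0487; 0.0581 with the slide as a block; 0.501 with an estimated correlation) asah1b fell. Normexp with the 75th percentile scaling turned these 5 lists upward, to 0.19 for pancreas, 0.53 for ribosomal proteins, 0.30 for lens, 0.62 for muscle and 0.19 for lysosome. Of these, pancreas (camera adjusted p = 0.337), lens (0.169) and lysosome (0.329) did not pass. Ribosomal proteins (0.000125) and muscle (0.00047) passed with the reversed shift. With quantile normalization after normexp, none of the 13 lists called in this comparison turned. Of the 13, 9 still passed and 4 did not, among them ribosomal proteins (-0.04) and muscle (-0.05). Without control 1 the shift was -0.21 for lens and -0.20 for ribosomal proteins.

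Of the lists that did not pass in this comparison, clock genes had a shift of 0.26 (adjusted p = 0.0642) with bhlhe41, per1b, nfil3-6 and bhlhe40 rising, and drug metabolism had -0.20 (adjusted p = 0.0883) with cyp2n13 (-1.27), cyp2ad2 (-0.88), gstr (-0.82) and cyp2p9 (-0.63) falling and the cytochrome reductase pora (0.71) rising. Neuromast support markers had 0.21 (adjusted p = 0.08): stat3 (SE 0.17, adjusted p = 0.00551) and the tight junction gene cldnb (1.39, SE 0.26) rose. Hair cell genes had -0.13 (adjusted p = 0.432), and of 17 only pvalb8 fell (-0.82, SE 0.19, adjusted p = 0.0366). Normexp reversed that fall without passing (0.68, limma adjusted p = 0.739), but with quantile normalization added it did not reverse it. Apoptosis had 0.08 (adjusted p = 0.528) with bcl2l1 (1.16), xiap (0.83), gadd45ab (1.09) and mcl1a (0.70) rising and sesn1 (-1.02) and sesn3 (-0.88) falling; its mean was 0.06 and its median -0.01. In the cholinergic list (0.01, adjusted p = 0.929) rapsn fell (-0.96, SE 0.17), with a mean of -0.01 and a median of -0.07. Glycolysis and hypoxia had 0.10 (adjusted p = 0.283) with igfbp1a, slc16a3b, hk2 and egln3 rising. Shifts without a call were found for cartilage and bone (-0.07; bglap fell, -1.34, adjusted p = 0.0626 with the slide as a block), cell cycle (-0.14), islet and enteroendocrine cells (0.08), epidermis (-0.07; krt18a.1 rose, 0.93), intestine (-0.04; slc10a2 and alpi.2 rose), ionocytes and pronephros (0.09; slc20a1b and lrp2a rose), leukocytes (-0.12), liver (-0.15; f9b rose and ces3 fell, adjusted p = 0.0523 and 0.0538 with the slide as a block), neurons and glia (-0.01), oxidative phosphorylation (-0.01), oxidative stress (-0.03) and photoreceptors (0.04). The mean and median of the ionocyte list (0.07, -0.02) and the photoreceptor list (0.02, -0.04) differed in sign, and the test pointed up for oxidative phosphorylation, whose mean was -0.02.

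In all, both compounds against control gave 1874 probes past the threshold, 1003 higher and 871 lower, of which 605 and 372 changed at least 2-fold. They came from 952 named genes (504 higher, 448 lower), and 627 have no gene symbol. At an unadjusted p under 0.05 there were 7086 probes (22.4%), and the groups did not overlap at 28.8% of probes, where chance gives 10%. With the slide as a block, 1196 were higher and 1080 lower, and leaving out 1 array gave between 786 and 1852 calls. Higher and lower probes numbered 944 and 981 with the 75th percentile taken over probes well above background on all arrays, 1065 and 1064 with a filter on all arrays, 1126 and 564 with median centring, and 1134 and 754 with quantile normalization. Set against the median of all probes (-0.41), normexp turned the direction of ahrra, pora, per1b, gata1a, lrp2a, sesn1, sesn3, myhc4, ces3, ela2l, cel.2, prss1 and rpl14 in this comparison. None of these differences passed with normexp (adjusted p = 0.248 to 0.98). With quantile normalization after normexp, no named gene turned. Camera called 13 gene lists, and other splits of these 6 arrays into 3 and 3 gave up to 11. Whether the 3 comparisons differ in their number of calls was not tested.

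Whether tacrine turned back the changes seen with neomycin was asked of the 37 probes called in neomycin against control. Of the 27 higher probes, 26 were also higher with both compounds than in controls; the 2 comparisons share the control arrays, which favours such an overlap, and the 0.855 that independent calls would give ignores this. Another step up from neomycin to both compounds was called for 11 of the 27, among them probes of fosab, junbb, atf3, dusp5 and mmp9, and 1 moved back, that of tnfb (-1.43). egr3, ptgs2b, igfbp1a, tnfrsf9a, mettl13 and grcc10 were not called in that step. Of the 10 lower probes, 7 moved back up, among them those of anxa3a, pet117 (1.78, SE 0.24) and asb5a (well above background only with both compounds), and faub, naaladl1 and the clone-named si:ch211-121a2.2 stayed called as lower than in controls. The last, named after its values were seen, had the largest fall of the 10 with neomycin (-8.38, SE 0.63, adjusted p = 0.00471). Its SD in controls was 1.57, and it was well above background on 1 of 3 neomycin arrays. From neomycin to both compounds it differed by 0.26 (SE 0.63, adjusted p = 0.876). Both steps hold the neomycin arrays, with opposite sign, so a probe picked for low values there tends to move back. Independent calls would give 0.18 of the 10, a value that ignores the shared arrays. In 20 data sets simulated with no effect the overlap was 0. That value decides nothing, because almost no probe is called where no effect is simulated.

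Across all 31671 probes, which are not independent replicates, the change from control to neomycin correlated with that from neomycin to both compounds with r = -0.32. In simulated groups with no effect, r was -0.50, because both differences hold the neomycin arrays with opposite sign; the simulations take arrays as independent and leave out the slide. The covariance was -0.0625 against -0.0372 in the simulations, a difference of -0.0253. The change with neomycin correlated with that of both compounds against control with r = 0.47, against 0.50 in the simulations, and the covariance was 0.0979 against 0.037, a difference of 0.0609. Over the 2118 probes called in any comparison, which are picked by these same changes, the first r was 0.02, and no simulated value was made for them. A spread of these differences was not estimated.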

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

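The normexp corrections on median signals, alone and with quantile normalization, were chosen after the results were seen; the other alternatives were not. Counts follow the order neomycin against control, both compounds against neomycin, both compounds against control (37, 844 and 1874 probes), and the cause of a change was not tested unless stated. The immediate early list passed in both comparisons with tacrine under all 27 alternatives for lists (shifts 0.67 to 1.06 and 1.05 to 1.58), and with neomycin alone in 26 of them (0.38 to 0.60), failing only with an estimated correlation. Among these alternatives, an adjusted p under 0.1 could not end a call, because it is the same test with a looser threshold. Normexp shifted the median of all probes by -0.35, -0.08 and -0.41 and called 0, 12 and 67 probes (the last 66 higher and 1 lower); limma gave 4883 probes at an unadjusted p under 0.05 where it called 0. It turned list shifts upward with neomycin alone for pancreas (0.45, camera adjusted p = 0.029), liver (0.47, 0.00493), ribosomal proteins (0.64, 3.62e-07) and muscle (0.60, 6.82e-05). It did so with both compounds against control for pancreas (0.19, 0.337), lens (0.30, 0.169), lysosome (0.19, 0.329), ribosomal proteins (0.53, 0.000125) and muscle (0.62, 0.00047). Set against the median of all probes, it also reversed grcc10 with neomycin (-0.15) and, with both compounds against control, nr4a3 (-0.18), loxl2a (-0.16), pvalb8 (0.68), ahrra (-0.09), pora (-0.05), sesn1 (0.43), sesn3 (0.39), per1b (-0.07), myhc4 (0.85), ces3 (0.78), ela2l (0.50), cel.2 (0.53), prss1 (0.76), gata1a (-0.04), lrp2a (-0.01) and rpl14 (0.36). None of these gene differences passed with normexp alone. With quantile normalization added, normexp called 7, 521 and 1093 probes (the last 710 higher, 383 lower). The ribosomal shift with neomycin was then 0.02, and no other called list and no named gene turned in any comparison. That shift was 0.01 with quantile normalization alone and 0.01 in the authors' matrix, which holds fewer probes and gave 18 calls with neomycin. In the last comparison median centring called 1126 higher and 564 lower, and the 75th percentile over probes above background on all arrays 944 and 981, against 1003 and 871. No filter gave 20 and 495 calls in the first 2 comparisons, and a filter on all 9 arrays gave 73 in the first and 1065 higher and 1064 lower in the last. Only the arrays compared, with fewer residual degrees of freedom, gave 1228 in the last. Trend and robust estimation gave 71 in the first, and array weights (0.377 to 4.32) gave 197, 3712 and 3004. An adjusted p under 0.1, looser by construction, gave 96, 1772 and 3499, and a change of at least 2-fold, stricter by construction, 539 and 977 in the last 2. Of 96 list tests, camera called 34, with an estimated correlation 2, and fry 19 (17 of the 34). The correlation between the 2 steps was -0.32, and 0.02 over the probes called in any comparison, which are picked by these changes and have no simulated value. Normexp on mean signals was not run, because the files hold no such column, and no block of scan day was fitted, because the slides were scanned on 1 day.

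The replicate number (slide) as a block gave 22 calls with neomycin (17 higher, 5 lower), of which 19 are among the 37 calls of the main model. Deviations from group means correlated between arrays of the same number by -0.083 to 0.26, over 0.1 in 6 of 9 pairs and best with their own number in 8 of 9; the labels do not pair the samples, so the numbers were not treated as pairs.

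Leaving out 1 array gave 11 to 65, 272 to 976 and 786 to 1852 calls, 30 to 40 lists and a correlation between the steps of -0.44 to -0.25. With neomycin, counts were 13 and 11 without controls 2 and 3, 20, 11 and 65 without neomycin 1, 2 and 3, and 62 without array 1 of both compounds. Both compounds against neomycin gave 434, 367 and 442 without neomycin 1, 2 and 3, and 272, 425 and 437 without the arrays of both compounds. Against control it was 1145, 1039 and 948 without controls 1, 2 and 3, and 786, 955 and 805 without the arrays of both compounds. Of the probes of named genes called in each comparison, 4 of 18, 22 of 53 and 32 of 77 passed without any 1 array, and of the lists 5 of 7, 9 of 14 and 10 of 13. Some genes have more than 1 probe among these. With neomycin, the 4 were probes of anxa3a, egr3 and fosab. There naaladl1 failed in 9 of 9 fits, junbb in 8, and atf3, mettl13, mmp9 and tnfb in 7 each. With neomycin, the ribosomal list failed without control 1 (adjusted p = 0.426) or neomycin 2 (0.0766), and liver without control 3 (0.0534), neomycin 2 (0.157) or neomycin 3 (0.0987). From neomycin to both compounds, inflammation failed without neomycin 3 (0.101) and ribosomal proteins without neomycin 1 (0.164). The stress response failed without neomycin 2 (0.0665), neomycin 3 (0.107) or array 3 of both compounds (0.0776). Cell cycle failed without neomycin 1 (0.245), neomycin 2 (0.0585) or array 3 of both compounds (0.148). Lysosome failed without neomycin 1 (0.109), neomycin 2 (0.0622), or arrays 2 (0.132) or 3 (0.125) of both compounds. Against control, targets of the aryl hydrocarbon receptor failed without control 2 (0.0591) or neomycin 1 (0.0502). Glucocorticoid genes failed without controls 2 (0.0591) or 3 (0.0892) or arrays 2 (0.0792) or 3 (0.0639) of both compounds. Lysosome failed without controls 1 (0.117) or 2 (0.0591), neomycin 1 (0.0579), 2 (0.0528) or 3 (0.0536), or arrays 2 (0.111) or 3 (0.0878) of both compounds.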

Other observations

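The tests of array brightness and of the place on the slide, the splits of the arrays by probes called and the search over gene families were chosen after the result was seen.

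The immediate early list lay higher with neomycin (5 of 41 genes passed; adjusted p = 0.126 with an estimated correlation) and again with both compounds against neomycin (20 of 41; 0.0262). Brighter arrays as the whole cause are argued against: the medians of the 41 genes (0.28 and 0.88) lay above those of matched lists (upper limits of the middle 95%, 0.07 and 0.08), and 0 of 10000 matched lists were as high. A single slide of larvae that differed is argued against as well, since the lowest mean change of the list on any slide in either step was 0.42. The place of each group on the slide cannot be told apart from treatment: 39% of the list (16 of 41) rose in both steps at an unadjusted p under 0.05, against 0.496% of the other 11285 genes, and place and group coincide. A response to the compounds stays open as a hypothesis, as do a response to handling and, with tacrine, a difference in DMSO, which were not tested.

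The probe of anxa3a lay far lower with neomycin alone. A stain that also covers the neighbouring spots is argued against, because the 8 nearest spots had a median change of -0.11 (-1.54 to 0.54). Neighbouring spots cannot show a fault of this spot alone. Neomycin arrays always lay at place 3 of the slide, so such a fault cannot be told apart from treatment. Stray spots are not excluded: of the 81 other sets of 3 arrays, 1 held a probe more than 4 log2 units below the other 6 arrays (highest number in a set 1). Of the 3 groups, 2 held 1 such probe each. That of the neomycin group is anxa3a itself, so these counts do not weigh against stray spots. Another 2 probes, without a gene symbol, also fell with neomycin and rose again with both compounds, and were well above background on no neomycin array and on all 6 others. The array has 1 probe for this gene, so a change of its transcript stays open and was not tested.

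Clock genes lay higher as a list with both compounds than with neomycin (camera adjusted p = 2.23e-05). The list did not pass with an estimated correlation (0.0548), and 5 of its 27 genes passed. A different time of harvest may move genes of day and evening apart. The mean of 7 day genes (0.66) less that of 3 evening genes (0.17) was 0.49, with a 95% interval of -0.16 to 1.14, so harvest time and treatment cannot be told apart on these arrays; few genes and wide intervals keep it open.

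Of 374 groups of gene symbols that share a stem, the tumour necrosis factor ligands (tnfsf) were over-represented among probes lower with both compounds than in controls, with 4 of 5 called (tnfsf10, tnfsf10l, tnfsf10l4 and tnfsf12; adjusted p = 0.000365), and 3 of 5 were lower than with neomycin alone (0.00121). Higher than with neomycin alone were 16 of 238 solute carriers (slc, 0.00296), 3 of 7 ccn genes (0.021), 3 of 7 socs genes (0.021), 4 of 17 dusp phosphatases (0.021) and 4 of 18 klf factors (0.0213). Members of a family share sequence, and cross-hybridization between them was not analysed here.

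The 6 arrays of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. In the order neomycin against control, both compounds against neomycin and both compounds against control, the real splits gave 37, 844 and 1874 probes (as many in 1, 1 and 1 of the 10) and the highest others 2, 6 and 2. For gene lists the real splits gave 7, 14 and 13 (as many in 7, 1 and 1 of the 10) and the highest others 11, 10 and 11.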
